A study of Mus musculus with 9 samples.

How the data were processed

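The series holds RNA sequencing of mouse embryonic fibroblasts, cells grown out of embryos of the C57BL/6 strain, that had been made senescent with gamma rays. Senescence is a lasting exit from the cell cycle in which cells stay alive and secrete many proteins. At day 10 after irradiation, per the labels' protocols, the cells received a lentivirus that carried a short hairpin RNA. shScr is a scrambled control hairpin, and shRela-1 and shRela-2 are independent hairpins against Rela, the gene of the p65 subunit of the transcription factor NF-kB. Each of the 3 groups has 3 replicates, 9 samples in all. The sequences of the hairpins are not given in the sources used here. Total RNA was purified on columns and made into libraries with the TruSeq RNA v2 kit, per the labels' protocols. This kit does not mark strand, so reads of overlapping genes on opposite strands cannot be told apart.

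The authors deposited raw counts per gene symbol, with one column per sample and no pooling. The submitters' processing notes name TopHat2 2.0.14, Bowtie2 2.2.6, featureCounts 1.4.6, Subread and the genome build mm10, without their roles or settings. The count table lists 24062 genes, of which 3924 had no count in any sample. Totals per sample ran from 49774667 to 67963506 counts. Low values in the deposited counts were even more often than odd. The value 1 occurred 2764 times and the value 2 occurred 7984 times. Whether mates of a read pair were counted separately, which would make the number of independent fragments smaller than the number of counts, is not given in the sources used here. Intervals given here do not cover that source of error, nor duplicate reads. All 9 columns were used.

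Samples were assigned to groups from their titles. The titles of the shScr samples carry a dataset tag, which may be that of another dataset of the study, and those of the shRela samples do not. Any library batch that goes with this tag has the same samples as the group, so the 2 cannot be told apart. Nothing in the labels says that the replicates came from separate cultures or embryos, so p-values measure only the spread between these samples, which may be technical. Replicate pairs differed far beyond sampling noise (chi-square per degree of freedom from 11.9 to 112), and none was treated as a duplicate. Within the controls, the pairs that include shScr replicate 2 gave 112 and 109, and the other pair gave 20.1.

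Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with its default settings (15369 genes), library sizes were scaled by TMM (factors 0.975 to 1.02), and 1 model with a mean per group was fitted to all 9 samples by glmQLFit. glmQLFTest, a two-sided test, gave 4 contrasts: each hairpin against shScr, the mean of both hairpins against shScr, and shRela-2 against shRela-1. Genes with a Benjamini-Hochberg adjusted p under 0.05 are said to have risen or fallen. Fold changes are on the log2 scale and are given with the standard error of the fit. CPM values, counts scaled to a common library size, were computed from TMM-scaled totals and are given as mean ± SD (n = 3 per group).

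Gene lists were fixed before the data were examined. The 23 lists cover secreted factors of senescent cells, NF-kB targets, other pathways of fibroblasts, and markers of other cell types that a culture of embryonic fibroblasts could hold. Each list was tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation between genes of 0.01. The 69 tests of 23 lists in the 3 contrasts against shScr were adjusted together, and the 23 tests of the contrast between hairpins separately. The same tests were run with an estimated correlation. With it, none of the 14 calls of the first family passed after adjustment (0 calls by camera, and 2 tests at an unadjusted p under 0.05), nor did any of the 4 calls between hairpins (0 calls, and 1 test at an unadjusted p under 0.05). In the first family fry, which asks whether the genes of a set move without comparing them with other genes, called 18 with a direction and 50 in either direction. The rule for the genes named was also fixed before the data were examined. It took Rela, Cdkn1a and Cxcl14. It took the 12 genes that rose and the 12 that fell with both hairpins by the largest margin, among genes with a mean log2 CPM of at least 1 and with the 6 knockdown samples all beyond the 3 control samples. Under the same floor, and with the groups compared fully apart, it took the 5 highest and 5 lowest called genes of each contrast between 2 groups, and it took up to 4 members of each list with the smallest p in the mean contrast. Genes whose symbol is a clone or model number were passed over, and 1 gene that the rule took is not reported here.

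Replicate numbers are given in the titles and are shared by the 3 groups. Deviations from the group means were positively correlated in all 9 pairs of same-numbered samples (0.189 to 0.415), and between -0.31 and 0.046 in pairs with different numbers. Each of the 9 samples correlated best with samples of its own number. The second principal component (19.5% of the variance) set replicate 1 apart from replicates 2 and 3 in every group, so the numbers pair the samples. A model with the replicate number as a block was fitted beside the planned one.

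Both hairpin contrasts use the same 3 controls. Groups without any change were therefore simulated 20 times from the control means, with the dispersions of the model without the block and again with those of the model with it. Sequence motifs were searched in the annotated 3' untranslated regions (UTRs) of 13757 tested genes, with Python 3.11.15. UTRs had to be at least 50 bases long. All 7-base motifs found in at least 100 genes (15861 motifs) were tested in a linear model of the fold change on motif presence, log2 UTR length, UTR GC content and the product of the last 2, with Bonferroni adjustment. Positions of genes come from the GENCODE mouse annotation of GRCm38, the assembly also called mm10.

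The methods were tested on simulated data. In counts simulated for 15369 genes in the contrast of shRela-1 with shScr, 83 of 100 genes changed 1.5-fold and 92 of 100 changed 2-fold were recovered, with 14 false calls among 189. For shRela-2 the numbers were 80 of 100 and 88 of 100, with 15 false calls among 183. A motif effect of 0.3 planted in 13757 genes was recovered as 0.309 and ranked first. Alternatives were DESeq2 1.42.0, limma voom, other scalings, other filters on low counts, fits of only the groups compared, the replicate block, and leaving out each sample in turn. Leaving out all replicates numbered 1 and a correction for GC content and transcript length were added after seeing the data.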

Results

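RNA was sequenced from irradiated, senescent mouse embryonic fibroblasts that carried a control hairpin (shScr) or 1 of 2 hairpins against Rela (shRela-1 and shRela-2), with 3 samples per group. The series belongs to a study of the proteins secreted under control of p21, the product of Cdkn1a, in stressed cells, and the comparison asks which transcripts depend on the p65 subunit of NF-kB in senescent cells. Total counts were 49774667, 67963506 and 62530781 in shScr replicates 1 to 3. They were 63663622, 64445863 and 62460501 with shRela-1, and 51071566, 61056637 and 55705353 with shRela-2.

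Rela, the target of both hairpins, fell to 16.0 ± 0.572% of the shScr mean with shRela-1 and to 16.3 ± 0.902% with shRela-2 (SD, n = 3). The gene lies on chromosome 19, 5637483 to 5648130, plus strand in mm10. It stood at 85.2 ± 1.84 CPM in shScr, 13.6 ± 0.487 CPM in shRela-1 and 13.9 ± 0.768 CPM in shRela-2. The percentages left were 16.6, 16.0 and 15.5 in shRela-1 replicates 1 to 3, and 17.3, 15.9 and 15.7 in shRela-2 replicates 1 to 3. On the log2 scale the changes were -2.64 ± 0.050 and -2.62 ± 0.050 (adjusted p = 8.73e-10 and 1.18e-09, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The hairpins differed by 0.026 in Rela, with a 95% interval from -0.087 to 0.14.

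**Figure D1:**
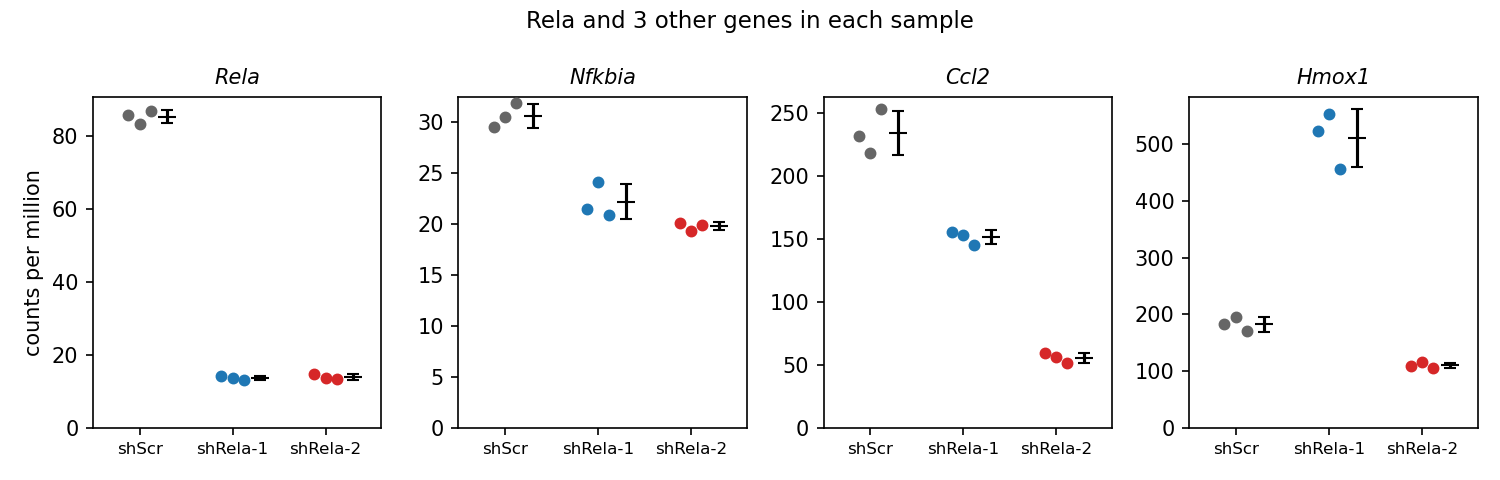
CPM of Rela, Nfkbia, Ccl2 and Hmox1 (vertical axes, each from 0) in the 9 samples by group (horizontal axis); points are replicates 1 to 3 from left to right, and the bar beside them is the mean ± SD (n = 3). Rela was at 85.2 CPM with shScr and at 13.6 and 13.9 CPM with the hairpins, and Hmox1 was at 511 CPM with shRela-1 and 110 CPM with shRela-2.

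Genes that NF-kB is known to switch on were among those that fell with both hairpins. Nfkbia, which encodes the inhibitor IkB-alpha, changed by -0.46 ± 0.063 with shRela-1 and by -0.63 ± 0.063 with shRela-2 (log2 fold change ± SE, here and below). Relb, a partner subunit of NF-kB, changed by -0.56 ± 0.082 and -0.60 ± 0.082, and Nfkb1, the p50 subunit, by -0.31 ± 0.039 and -0.26 ± 0.039. Of the 35 tested members of the list of NF-kB feedback and canonical targets, 11 fell with shRela-1, 15 with shRela-2 and 15 in the mean of both hairpins (12, 17 and 18 when adjusted over the list alone). No member rose over all genes tested (0 by edgeR, DESeq2 and limma voom in each of these contrasts), although 4 were higher with shRela-1 at an unadjusted p under 0.05 and 1 rose with it when adjusted over the list alone. With the replicate block, 5 rose with shRela-1 and 2 with shRela-2 and in the mean. With shRela-1, 2 rose without shScr replicate 1 or shRela-1 replicate 2, and 1 without shRela-2 replicate 1. With shRela-2, 1 rose without shScr replicate 2 or shRela-2 replicate 2. The list's medians were -0.15, -0.26 and -0.23 (camera, adjusted p = 0.0103, 1.83e-04 and 2.41e-05). With an estimated correlation the adjusted p were 0.828, 0.668 and 0.668.

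Secreted factors of senescent cells, the SASP, fell as a list with shRela-2 and in the mean of both hairpins. Ccl2, a chemokine that attracts monocytes, fell from 234 ± 17.6 CPM to 151 ± 5.51 CPM with shRela-1 and to 55.7 ± 3.95 CPM with shRela-2. Plau, which encodes urokinase, changed by -0.54 ± 0.10 and -1.49 ± 0.11. Ccl7, a related chemokine, fell with shRela-2 (-1.78 ± 0.13), and its value with shRela-1 was -0.03 ± 0.13. Ptges, a prostaglandin synthase, fell with shRela-1 (-0.72 ± 0.049) and was at 0.14 ± 0.048 with shRela-2 (adjusted p = 0.0511, or 0.00576 with the replicate block, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Of 48 tested SASP factors, 12 fell and 4 rose with shRela-1, and 19 fell and 4 rose with shRela-2 (12 and 4, and 20 and 5, adjusted over the list alone). With the replicate block 9 rose with shRela-1, and 29 fell and 8 rose with shRela-2. In the mean of both hairpins 15 fell and 2 rose (17 and 2 adjusted over the list alone), and 32 and 5 with the replicate block. Without shScr replicate 1 or shRela-1 replicate 3, 1 rose. The medians were -0.09, -0.42 and -0.27 (camera, adjusted p = 0.157, 0.00493 and 6.22e-04). With an estimated correlation the adjusted p were 0.945, 0.828 and 0.828. The list's difference between hairpins had a median of -0.22 (camera, adjusted p = 0.0819). With the replicate block, camera's adjusted p was 0.0192, or 0.596 with an estimated correlation as well. Markers of macrophages and blood cells had a median of -0.20 with shRela-2 (camera, adjusted p = 0.245). With the block 11 of 18 fell, and camera's adjusted p was 0.00504, or 0.491 with an estimated correlation as well.

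**Figure D2:**
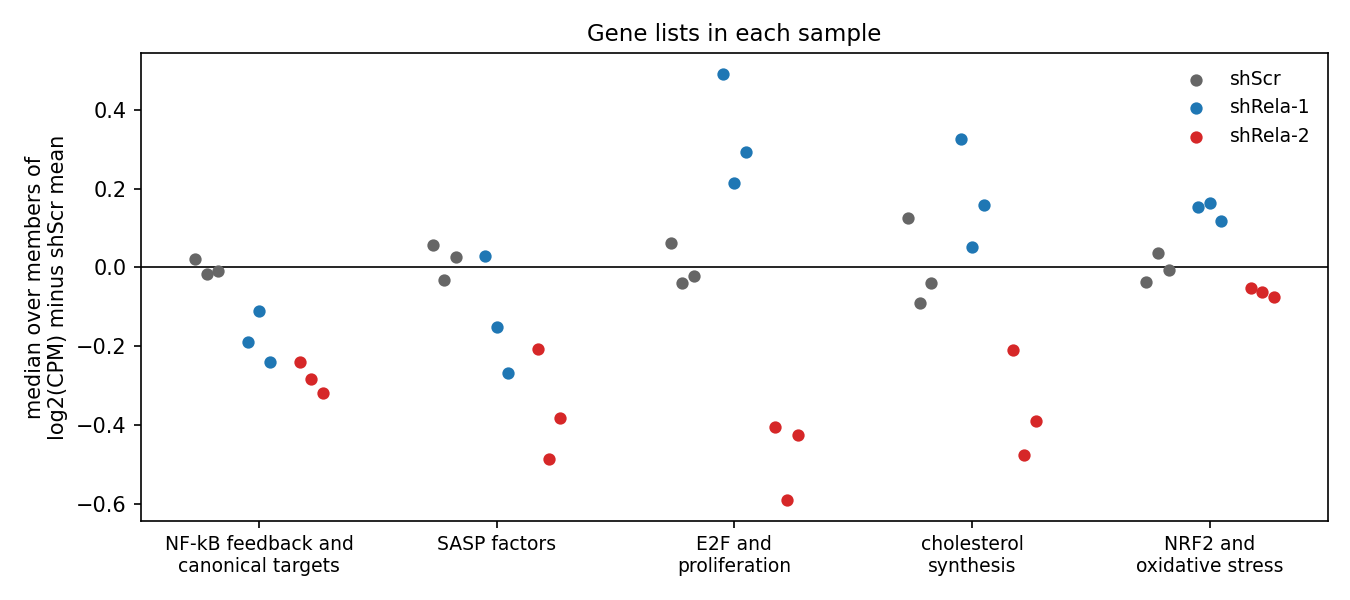
Median over the tested members of 5 gene lists (horizontal axis) of log2 CPM minus the shScr mean (vertical axis), with 1 point per sample, colored by group and ordered from replicate 1 to 3 within a group. NF-kB targets lie between -0.11 and -0.32 in the 6 knockdown samples, and proliferation genes lie between 0.21 and 0.49 with shRela-1 and between -0.40 and -0.59 with shRela-2.

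The genes named next changed the same way with both hairpins. Gjb2, a gap junction subunit, changed by -0.96 ± 0.12 with shRela-1 and -1.56 ± 0.13 with shRela-2. Tnfsf11, which encodes the cytokine RANKL, changed by -0.94 ± 0.12 and -1.23 ± 0.12, Tnfrsf26, a TNF receptor family member, by -1.02 ± 0.19 and -1.53 ± 0.20, and Mmp9, a gelatinase, by -0.92 ± 0.24 and -0.87 ± 0.24. Serpina3g, a serpin of a large family of close paralogs whose reads may be split, changed by -0.89 ± 0.098 and -1.10 ± 0.099. The kinase gene Yes1 (-1.18 and -1.15), the endoplasmic reticulum gene Erlin2 (-1.74 and -0.84), Dnajc19 (-0.82 and -1.39), Lancl3 (-0.95 and -0.80), Amot (-0.79 and -0.88) and the sterol gene Msmo1 (-0.75 and -1.38) also fell with both. Among the genes that rose with both were Ildr2 (0.83 ± 0.12 and 1.12 ± 0.12), Tdrp (0.79 and 1.16), the ketone body enzyme Bdh1 (0.74 and 0.89), Ostm1 (0.73 and 0.81) and the glycosyltransferase gene Mgat4b (0.78 and 0.71). Herpud1, an endoplasmic reticulum stress gene, changed by 0.66 and 0.59, Reck, an inhibitor of matrix proteases, by 0.54 and 0.71, and Ulbp1, a ligand of the NK cell receptor NKG2D, by 0.61 and 0.69. The rule also took Sprr3 (0.73 and 1.39), Fam57a (0.64 and 0.59), Agpat9 (0.65 and 0.58) and Uts2b (0.57 and 0.61). Across these genes other than Rela, adjusted p ran from 4.25e-08 for Erlin2 with shRela-1 to 0.0365 for Agpat9 with shRela-2 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment).

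Calls of 4 of these genes were lost without single libraries (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment throughout). For Agpat9 with shRela-1 the adjusted p was 0.0695 without shScr replicate 2, 0.0969 without shScr replicate 3, 0.0895 without shRela-1 replicate 1 and 0.051 without shRela-1 replicate 2. For Agpat9 with shRela-2 it was 0.0894 and 0.133 without shScr replicates 2 and 3, 0.0509 without shRela-1 replicate 2, and 0.13 and 0.0546 without shRela-2 replicates 1 and 2. For Mmp9 with shRela-1 it was 0.0553 and 0.056 without shScr replicates 1 and 3, and 0.0639 and 0.0645 without shRela-1 replicates 2 and 3. For Mmp9 with shRela-2 it was 0.0585 and 0.0553 without shScr replicates 1 and 3. For Ulbp1 with shRela-1 it was 0.063 and 0.0528 without shScr replicates 2 and 3, and 0.0521 and 0.0539 without shRela-1 replicates 1 and 3. For Lancl3 with shRela-2 it was 0.0558 without shScr replicate 3 and 0.0534 without shRela-2 replicate 2. Exons of Dnajc19 overlap those of Fxr1 on the opposite strand, exons of Fam57a those of Gemin4 and Glod4, and exons of Lancl3 those of Gm14862. The 3' UTRs of Yes1, Erlin2, Tnfsf11 and Lancl3 hold AGGTGTA, the motif most associated with lower expression under shRela-1. Those of Tnfrsf26, Tnfsf11, Lancl3, Amot and Msmo1 hold GAAGCTA, its counterpart under shRela-2, as do those of Ildr2 and Ulbp1.

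In all, 1070 genes changed in the same direction with both hairpins, of which 633 rose and 437 fell. Independent lists of these sizes would share 291 rising and 295 falling genes. In opposite directions, 377 genes rose with shRela-1 and fell with shRela-2, and 403 did the reverse, against 291 and 295 for independent lists. Fold changes under the 2 hairpins correlated weakly across genes, which are not independent replicates (Pearson's r = 0.176, Spearman's rho = 0.131), and 55.4% of genes had the same sign. Simulated unchanged groups against the same controls gave a mean r of 0.505 and the same sign in 66.6% of genes. They gave at most 0 genes called in the same direction by edgeR with the dispersions of the unblocked model (at most 182 at an unadjusted p under 0.05, against 1753 observed) and at most 7 with those of the blocked model. The covariance of the fold changes was 0.0222. The simulated covariance was 0.027 with the unblocked dispersions and 0.0158 with the blocked ones, so the difference was -0.00478 or 0.00644. The 3 controls could not be split into parts of at least 2, so part of the excess in overlap may come from the shared controls. With the replicate block, 2058 genes changed in the same direction (1154 rose and 904 fell) and 1529 in opposite directions (837 and 692), and without shScr replicate 3 the numbers were 693 and 476.

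**Figure D3:**
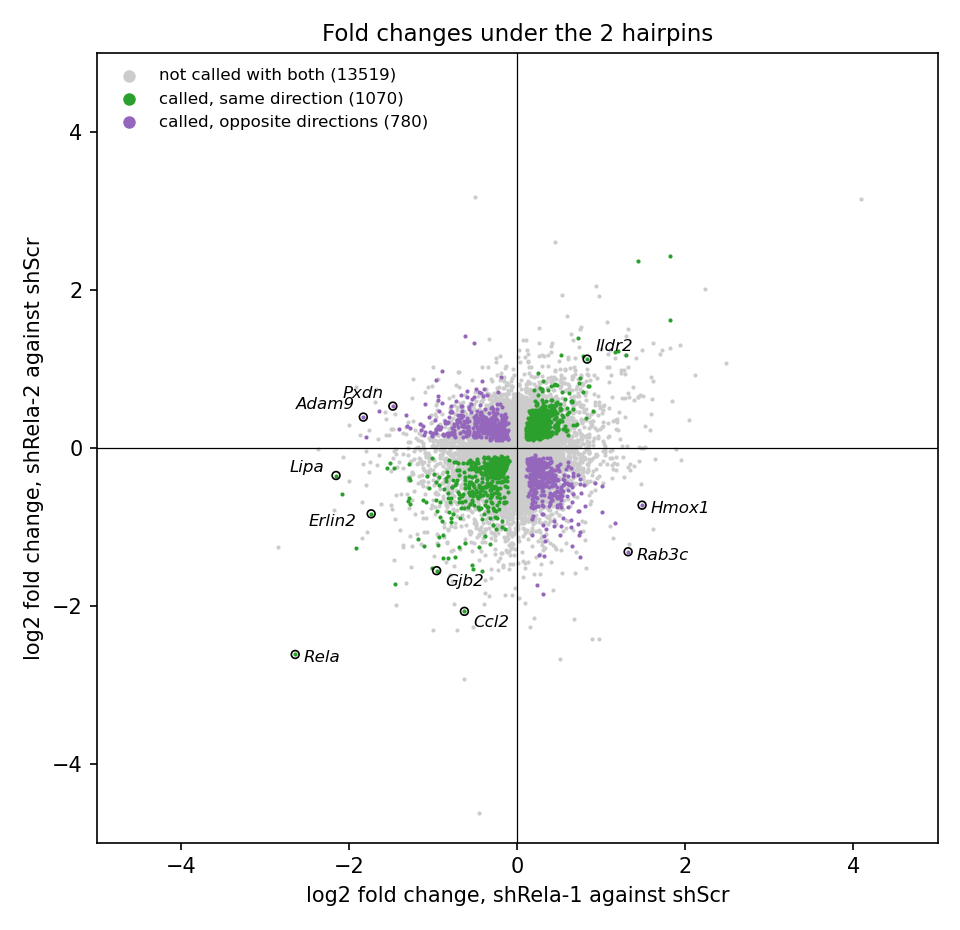
Log2 fold change against shScr of the 15369 tested genes with shRela-1 (horizontal axis) and shRela-2 (vertical axis); green points are the 1070 genes called with both hairpins in the same direction and purple points the 780 called in opposite directions (3 samples per group). Rela lies at -2.64 and -2.62, and Hmox1 at 1.48 and -0.73.

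Averaged over both hairpins, 3507 genes differed from shScr, of which 1638 rose and 1869 fell, and 17 rose and 36 fell by more than 2-fold (26 and 58 with the replicate block). On this average Ccl2 changed by -1.35 ± 0.054 and Plau by -1.02 ± 0.087. Cdkn1a, which encodes p21, rose from 964 ± 43.9 CPM to 1149 ± 93.4 CPM with shRela-2 (0.25 ± 0.063, adjusted p = 0.0107, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Its value with shRela-1 was 0.13 ± 0.063 (adjusted p = 0.169, or 0.00192 with the replicate block, by the same edgeR test). Cxcl14, a chemokine of interest to the study, was at 230 ± 16.2 CPM in shScr, 241 ± 12.7 CPM in shRela-1 and 162 ± 13.2 CPM in shRela-2. It fell with shRela-2 (-0.51 ± 0.069, adjusted p = 3.54e-04), was at 0.07 ± 0.069 with shRela-1 (adjusted p = 0.513), and differed between hairpins by -0.58 ± 0.069 (adjusted p = 7.59e-05, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The count of 3507 became 5763 with the replicate block, 2329 without shScr replicate 3, and 440 when the 6 knockdown samples were fitted as 1 group, so that the difference between hairpins entered the spread.

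With shRela-1, genes of proliferation were among those that rose. Of the 52 genes of the E2F and proliferation list, 24 rose and the others did not pass the test (31 rose and 1 fell when adjusted over the list alone, and 38 and 1 with the replicate block). Without shRela-1 replicate 1 or shRela-2 replicate 1, 1 member fell. Examples were the replication helicase gene Mcm2 (0.50 ± 0.071) and the ribonucleotide reductase genes Rrm2 (0.53 ± 0.067) and Rrm1 (0.25 ± 0.045). The list's median was 0.32 (camera, adjusted p = 3.27e-09, and 0.828 with an estimated correlation). Genes of the NRF2 and oxidative stress list rose in 9 of 27 members and fell in 2 (10 and 2 adjusted over the list alone, and 15 rose with the block), with a median of 0.13 (camera, adjusted p = 0.0161, and 0.828 with an estimated correlation). Hmox1, heme oxygenase, rose from 183 ± 12.7 to 511 ± 50.3 CPM, and Ftl1, a ferritin subunit with pseudogenes that may take part of its reads, changed by 0.48 ± 0.046. Tkt, a transketolase, fell (-0.59 ± 0.042). Without shScr replicate 1 or shRela-1 replicate 2, 1 member of the list fell.

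Genes of antigen presentation were among those that fell with shRela-1. In the list of MHC class I antigen presentation, 5 of 21 members fell and 1 rose (7 and 1 adjusted over the list alone, and 10 and 2 with the block), for example Tapbpl (-0.45 ± 0.089) and H2-T23 (-0.79 ± 0.077), one of a family of close paralogs whose reads may be split. The median was -0.29 (camera, adjusted p = 0.0314, and 0.945 with an estimated correlation). This call was lost without shScr replicate 1 (adjusted p = 0.0669), shRela-1 replicate 1 (0.0689) or shRela-1 replicate 3 (0.0821). Without shRela-2 replicate 1, 8 members fell, and without shScr replicate 1, 2 rose. Ikbkb, a kinase that activates NF-kB, changed by -1.30 ± 0.047 with shRela-1 and had -0.09 ± 0.046 with shRela-2. Its list, the components of NF-kB signalling, did not pass camera with shRela-1 (median -0.03, adjusted p = 0.371). By fry with a direction the list passed (adjusted p = 5.49e-04). Of its 34 members 9 fell and 4 rose (the same numbers adjusted over the list alone). Among the 25 members with neither AGGTGTA nor GAAGCTA, 3 fell and 3 rose. Without shScr replicate 1, 2 or 3 or shRela-1 replicate 1, 2 members of this list rose. Cflar, an inhibitor of caspase activation, changed by -0.67 ± 0.036, and Irf1, whose exons overlap Gm17334 on the other strand, by -1.15 ± 0.11. The largest falls under the naming rule after Rela were those of Lipa, lysosomal acid lipase (-2.16 ± 0.087), the protease gene Adam9 (-1.83 ± 0.037), Rtn4, which encodes Nogo (-1.80 ± 0.047), and Upk1b (-1.80 ± 0.31). Among the largest rises were those of Kcnj6 (1.52 ± 0.16), Hmox1 (1.48 ± 0.075), Ccdc81 (1.47 ± 0.21) and Rab3c (1.32 ± 0.14). The 3' UTRs of Lipa, Rtn4, Upk1b, Ikbkb and Ptges hold AGGTGTA. Rtn4 shares exonic sequence with Eml6 on the opposite strand.

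Genes of fibrillar and basement membrane matrix rose with shRela-1 in 11 of 50 members and fell in 2 (the same numbers when adjusted over the list alone, and 29 and 6 with the replicate block). Ogn, which encodes the small proteoglycan osteoglycin, changed by 0.71 ± 0.064, and the collagen gene Col5a3 by -0.57 ± 0.089. The median was 0.10 (camera, adjusted p = 0.0355, and 0.95 with an estimated correlation). The adjusted p was 0.174 without shScr replicate 1, 0.0905 without shScr replicate 2, 0.0643 without shRela-1 replicate 2 and 0.169 without shRela-1 replicate 3. The number of rising members was 7 without shScr replicate 1 and 6 without shRela-1 replicate 2 or 3.

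Over all genes, 3799 changed with shRela-1, of which 1887 rose and 1912 fell, and 57 rose and 114 fell by more than 2-fold. With the replicate block 6034 genes changed.

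With shRela-2, genes of proliferation were among those that fell. In the E2F and proliferation list 35 of 52 genes fell and 1, Rrm1 (0.21 ± 0.045), rose (39 and 1 adjusted over the list alone). E2f8, a repressor of the E2F family, changed by -0.86 ± 0.13, while Mcm2 was at 0.04 ± 0.072 and Rrm2 at -0.03 ± 0.067. The median was -0.49 (camera, adjusted p = 4.90e-10, and 0.828 with an estimated correlation). Cholesterol synthesis genes fell in 16 of 25 members and rose in 1 (17 and 1 adjusted over the list alone), for example Msmo1 (-1.38 ± 0.088), Sqle, squalene epoxidase (-0.74 ± 0.051), and Stard4 (-0.54 ± 0.093). Their median was -0.34 (camera, adjusted p = 1.47e-04, and 0.945 with an estimated correlation).

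Complement and acute phase genes fell in 8 of 18 members with shRela-2 (9 fell and 1 rose when adjusted over the list alone). C3, the central complement component, changed by -1.20 ± 0.13, and the serum amyloid gene Saa3 by -2.31 ± 0.38. The median was -0.44 (camera, adjusted p = 0.0197, and 0.828 with an estimated correlation). The adjusted p was 0.0591 without shScr replicate 2, and 5 members fell without shScr replicate 1, shScr replicate 2 or shRela-2 replicate 3. Markers of macrophages and blood cells had a median of -0.20 in the same contrast, as given above.

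Lysosome genes rose with shRela-2 in 15 of 39 members and fell in 4 (the same numbers when adjusted over the list alone). Neu1, a sialidase, changed by 0.72 ± 0.050 and Atp6v0d1, a subunit of the proton pump, by -0.59 ± 0.051. The median was 0.10 (camera, adjusted p = 0.0199, 0.828 with an estimated correlation, and 0.0643 without shScr replicate 2). In the mean of both hairpins 11 rose and 5 fell (17 and 5 adjusted over the list alone), with a median of 0.10 (camera, adjusted p = 0.0197, 0.828 with an estimated correlation, and 0.0734 without shScr replicate 2). The count of 11 was 25 with the replicate block and 7 without shScr replicate 2.

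Under the naming rule, the largest falls with shRela-2 after Rela were those of Tnfsf18, the ligand of the receptor GITR (-2.42 ± 0.65), the chemokine genes Ccl20 (-2.31 ± 0.29), Ccl2 (-2.07 ± 0.067) and Cxcl1 (-1.90 ± 0.59). The largest rises were those of the histone gene Hist1h2bg (1.93 ± 0.61), the cornified envelope genes Lce1h (1.42 ± 0.11), Sprr3 (1.39 ± 0.16) and Lce1f (1.32 ± 0.15), and Tdrp (1.16 ± 0.079). Hist1h2bg, Lce1h and Lce1f belong to families of near-identical genes, and their values are uncertain. The calls of 3 of these genes depended on single libraries. Without shScr replicate 1, 2 or 3 the adjusted p was 0.0803, 0.0793 and 0.105 for Hist1h2bg and 0.0618, 0.0852 and 0.05 for Cxcl1 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It was 0.0541 for Hist1h2bg without shRela-1 replicate 3, and 0.072 and 0.108 for Cxcl1 without shRela-2 replicates 1 and 3. Without shRela-2 replicate 1 the change of Hist1h2bg was 0.53. For Tnfsf18 the adjusted p was 0.0589 without shScr replicate 2, 0.0506 without shRela-2 replicate 1 and 0.0552 without shRela-2 replicate 3. By limma voom it was 0.176 for Hist1h2bg, 0.0861 for Cxcl1 and 0.103 for Tnfsf18, and by edgeR fitted to only the groups compared it was 0.0653 for Hist1h2bg. The 3' UTRs of Tnfsf18 and Sqle hold GAAGCTA, as do those of Msmo1 and Stard4.

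Over all genes, 4742 changed with shRela-2, of which 2371 rose and 2371 fell, and 41 rose and 151 fell by more than 2-fold.

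The hairpins differed from each other in more genes than either did from the control. Between them 6134 genes differed, of which 3071 were higher and 3063 lower with shRela-2, and 222 were higher and 316 lower by more than 2-fold. Proliferation genes were lower with shRela-2 in 47 of 52 members (48 adjusted over the list alone), with a median difference of -0.82 (camera, adjusted p = 6.25e-17, and 0.465 with an estimated correlation). Cholesterol synthesis genes were lower in 17 and higher in 2 of 25 (18 and 2 adjusted over the list alone), with a median of -0.55 (camera, adjusted p = 1.37e-04, and 0.819 with an estimated correlation). NRF2 genes were lower in 15 and higher in 2 of 27 (the same numbers adjusted over the list alone, and 4 higher with the replicate block), with a median of -0.25 (camera, adjusted p = 0.0113, and 0.465 with an estimated correlation). Hmox1 differed by -2.21 ± 0.077.

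Antigen presentation genes were higher with shRela-2 than with shRela-1 in 6 and lower in 1 of 21 members (the same numbers adjusted over the list alone, and 12 higher with the replicate block), with a median of 0.30 (camera, adjusted p = 0.0484, and 0.819 with an estimated correlation). H2-T23 differed by 0.92 ± 0.077. This list's adjusted p was 0.0554 without shScr replicate 1, 0.0549 without shScr replicate 2, 0.0537 without shRela-1 replicate 1, 0.0657 without shRela-1 replicate 3 and 0.134 without shRela-2 replicate 1, and 10 members were higher without shRela-2 replicate 3. Adam9 (2.22 ± 0.037), C1d (2.10 ± 0.068), Lce1h (2.04 ± 0.12), the peroxidasin gene Pxdn (2.01 ± 0.062) and the respiratory chain gene Ndufb2 (2.00 ± 0.10), whose exons overlap Braf on the opposite strand, were the highest in shRela-2 relative to shRela-1 under the naming rule. Tnfsf18 (-3.31 ± 0.65), Rab3c (-2.64 ± 0.16), Hmox1 (-2.21 ± 0.077), Tspan2 (-2.16 ± 0.080) and the kinetochore gene Nuf2 (-2.13 ± 0.13) were the lowest. Across these 10 genes adjusted p ran from 2.74e-10 for Adam9 to 0.00203 for Tnfsf18 (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The 3' UTRs of C1d and Ndufb2 hold AGGTGTA, and those of Tnfsf18, Rab3c, Tspan2, Nuf2 and Ndufb2 hold GAAGCTA.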

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

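The test of unequal depletion of the Rela transcript was chosen only after the result was seen. Results in this part stood out because the 2 hairpins, which share a target, differed in their effect, by a test of the difference itself.

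Between the hairpins 6134 genes differed (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and 780 genes moved in opposite directions against shScr (476 without shScr replicate 3, 1529 with the replicate block). Unequal depletion of the Rela transcript is argued against by its difference between hairpins, 0.026 on the log2 scale (95% interval from -0.087 to 0.14). The p65 protein was not measured in these data, so unequal loss of the protein stays open. GC content or gene length is argued against by a count that stayed at 1.01 times that of the blocked model after correction. Seed-matched silencing, in which a short stretch of the guide strand pairs with a 3' UTR, may account for part of the difference: among 15861 motifs tested across genes (n = 13757 genes, which are not independent replicates), AGGTGTA was the most associated with lower expression under shRela-1 (1120 genes, effect -0.23, t = -21.02, Bonferroni p = 2.28e-92) and GAAGCTA under shRela-2 (1239 genes, effect -0.23, t = -21.38, p = 1.26e-95). Both motifs also occur in the Rela coding sequence, as a hairpin against Rela requires, although 16.1% of the tested motifs do so: AGGTGTA in exon 8 (chromosome 19, 5641473 to 5641479, plus strand, GRCm38) and GAAGCTA in exon 11 (chromosome 19, 5647255 to 5647261). Matches to these 2 motifs in the 3' UTR are not the whole difference. Of the 11594 genes with neither motif, 39.6% (4594 genes) differed between hairpins, against 53.4% of the 2163 genes with a motif. Overlapping motifs, such as GGTGTAA under shRela-1 (t = -20.53) and TGAAGCT under shRela-2 (t = -19.66), were not removed from these genes. Matches to them, effects that spread from silenced genes, and any effect of the viruses themselves stay open and untested.

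The 7-base motifs separated the hairpins. Genes with AGGTGTA had an effect of 0.0019 under shRela-2 (t = 0.17), and genes with GAAGCTA one of 0.0069 under shRela-1 (t = 0.66). The largest t of any motif associated with higher expression was 4.01 and 4.19. AGGTGTA was in the 3' UTR of 412 of the 1815 genes that fell with shRela-1 (22.7%, against 5.93% of the other genes, odds ratio 4.66, Fisher's exact test, two-sided, p = 4.03e-99). GAAGCTA was in 469 of the 2240 genes that fell with shRela-2 (20.9% against 6.69%, odds ratio 3.70, p = 8.78e-84 by the same exact test). Both motifs were picked from these same fold changes, so these shares describe the selected motifs and are no separate test.

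Of the 52 genes of the E2F and proliferation list, 24 rose with shRela-1, and 35 fell and 1 rose with shRela-2. The list's median difference between hairpins was -0.82 (camera, adjusted p = 6.25e-17, and 0.465 with an estimated correlation). Direct matches to AGGTGTA or GAAGCTA in these genes are argued against by the 47 of 52 members with neither motif. Their median difference was -0.81 (quartiles -1.02 and -0.63). Members with overlapping motifs, such as GGTGTAA (effect -0.25 under shRela-1) or TGAAGCT (effect -0.175 under shRela-2), were not removed. A difference of 1 library is argued against by the weakest median with any library left out, -0.73. Unequal depletion of the Rela transcript is argued against by its difference of 0.026 between hairpins, and the protein was not measured. Indirect effects of genes silenced through seed matches, or cultures that differed in their share of dividing cells, could each move such a list, and neither was tested. The opposite directions leave open which hairpin, if either, shows an effect of Rela on proliferation.

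Cholesterol synthesis genes differed between hairpins by a median of -0.55 (camera, adjusted p = 1.37e-04, and 0.819 with an estimated correlation). The list of NRF2 and oxidative stress genes had a median difference of -0.25 (camera, adjusted p = 0.0113, and 0.465 with an estimated correlation). MHC class I antigen presentation genes had a median difference of 0.30 (camera, adjusted p = 0.0484, and 0.819 with an estimated correlation), and the adjusted p was 0.0554 without shScr replicate 1, 0.0549 without shScr replicate 2, 0.0537 without shRela-1 replicate 1, 0.0657 without shRela-1 replicate 3 and 0.134 without shRela-2 replicate 1.

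Of the 10 splits of the 6 knockdown samples into 3 and 3, 1, the real one, called as many genes. In a fit of these samples alone the real split called 5790 genes and the highest of the other splits 0 (edgeR; 7152 and 633 at an unadjusted p under 0.05). The 3 other splits that took each replicate number once, as the real one does, called at most 0 genes by edgeR and at most 104 at an unadjusted p under 0.05. With 10 splits the share cannot fall under 0.05.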

How the results depend on the processing

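Leaving out all replicates numbered 1 and the correction for GC content and length were chosen only after the results were seen. The numbers of changed genes given first are 3799 for shRela-1, 4742 for shRela-2, 3507 for the mean of both hairpins, 1070 for both hairpins in the same direction and 6134 between hairpins. The replicate block raised them to 6034, 6830, 5763, 2058 and 7974, and kept 3797 of the 3799, 4738 of the 4742, 3507 of the 3507 and 6124 of the 6134. The block with the correction for GC content and length, which were known for 14666 of the 15369 genes (95.4%), gave 6200 for shRela-1, 5970 for the mean and 2197 for both in the same direction. Beyond the results where a blocked value is given, the block changed no other call among the list tests and among the genes in the contrasts for which the text gives a fold change. Fitting only the groups compared gave 440 for the mean contrast, because the 6 knockdown samples then share 1 mean and the difference between hairpins enters the spread. DESeq2 called 4161, 4989, 3865 and 6248 genes, and limma voom 3902, 4718, 3560 and 6137, in the contrasts of shRela-1, shRela-2, the mean and between hairpins. Leaving out 1 sample at a time gave 2745 to 3824 for shRela-1, 3766 to 4757 for shRela-2, 2329 to 3335 for the mean, 693 to 943 for both in the same direction and 5280 to 6152 between hairpins. The lowest values of the mean and of both in the same direction came without shScr replicate 3, and for these fits the lower number of samples is part of the change. Without the replicates numbered 1 the numbers were 3398, 4106, 3043, 877 and 5566. No scaling moved the share of higher among called genes by as much as 10 percentage points. Of the list tests, 14 of 69 passed with the preset correlation and 14 with DESeq2 size factors. With an estimated correlation 0 passed (camera; 2 at an unadjusted p under 0.05), whereas fry called 18 with a direction (12 of the 14 among them) and 50 in either direction. The block gave 21 list calls, which kept all 14, leaving out 1 sample gave 11 to 17 (10 to 14 kept), and leaving out the replicates numbered 1 gave 14 (13 kept; the call lost was that of MHC class I antigen presentation with shRela-1, at 0.0619). Except where a reason is given, the cause of these moves was not tested. For the 173 results of single named genes, 3282 values under alternatives were computed, of which 0 reversed a direction and 107 no longer passed the test. The call was the same under all alternatives run for 147 of the 173. Depth limited genes of few counts: 3 counts correspond to 0.0441 CPM in the deepest sample and 0.0603 CPM in the shallowest.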

Other observations

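The test of control libraries from separate cultures was chosen only after the result was seen.

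Several stress and growth genes outside the groups described above changed while their lists did not pass camera. The p53 target Sesn2, a sensor of stress and nutrients, rose with both hairpins (0.54 ± 0.061 and 0.33 ± 0.061), as did Tnfrsf10b, a death receptor for TRAIL (0.28 ± 0.033 and 0.21 ± 0.033), and Bad, a promoter of apoptosis (0.23 ± 0.050 and 0.21 ± 0.050). Zmat3, another p53 target, fell with shRela-1 (-0.80 ± 0.055). The p53 targets as a list had medians of 0.09 with shRela-1 and 0.03 with shRela-2 (camera, adjusted p = 0.0993 and 0.914). For shRela-1 with the replicate block, camera's adjusted p was 0.0284, or 0.507 with an estimated correlation as well. Hsp90b1, a chaperone of the endoplasmic reticulum, fell with shRela-1 (-1.30 ± 0.042), and Hyou1, another, rose with both (0.22 ± 0.036 and 0.44 ± 0.036). The unfolded protein and integrated stress response list had medians of 0.16 with shRela-1 and -0.01 with shRela-2 (camera, adjusted p = 0.0732 and 0.666). For shRela-1 with the block, camera's adjusted p was 0.0273, or 0.63 with an estimated correlation as well. Camera's direction for shRela-2 was up although the median and the mean (-0.04) were below 0. CDK inhibitors and the RB family had medians of 0.05 with shRela-1 and -0.01 with shRela-2 (camera, adjusted p = 0.619 and 0.988), with camera's direction up for shRela-2. Apoptosis regulators had means of -0.06 and -0.01 (camera, adjusted p = 0.846 and 0.982), with camera's direction up for shRela-1. Components of NF-kB signalling had medians of -0.03 with shRela-1 and -0.02 with shRela-2 (camera, adjusted p = 0.371 and 0.668). Camera's direction was up for shRela-2. Fry with a direction gave this list adjusted p of 5.49e-04 with shRela-1 and 0.0164 with shRela-2. Among its members Bcl10 fell with shRela-1 (-0.54 ± 0.050).

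The same held for genes of TGF-beta signalling and matrix turnover. Inhba, which encodes a subunit of activin, fell with both hairpins (-0.45 ± 0.059 and -0.57 ± 0.059), and Tgfbr2, a receptor of TGF-beta, rose with both (0.27 ± 0.049 and 0.44 ± 0.049). Mylk, a kinase of the myosin light chain, rose with shRela-1 (1.02 ± 0.085). The contractile and TGF-beta response list had medians of 0.17 with shRela-1 and -0.07 with shRela-2 (camera, adjusted p = 0.177 and 0.716). For shRela-1 with the block, camera's adjusted p was 0.0388, or 0.82 with an estimated correlation as well. Adam17, a sheddase of TNF, rose with both hairpins (0.22 ± 0.035 and 0.26 ± 0.035), and the protease gene Adam12 fell with shRela-1 (-0.49 ± 0.079). Matrix proteases and inhibitors had medians of 0.04 with shRela-1 and 0.05 with shRela-2 (camera, adjusted p = 0.786 and 0.968), while their means were -0.02 and -0.10. The type I interferon response had medians of -0.28 with shRela-1 and 0.13 with shRela-2 (camera, adjusted p = 0.216 and 0.846). Replicate 1 stood apart in both groups. Against the shScr mean, medians in replicates 1 to 3 were -0.69, -0.04 and -0.16 with shRela-1. With shRela-2 they were 0.63, -0.08 and -0.39. Lists described above for 1 hairpin had these medians with the other: cholesterol synthesis 0.18 with shRela-1 (camera, adjusted p = 0.157, or 0.0383 with the block), lysosome 0.09 with shRela-1 and a mean of -0.01 (0.167, or 0.039 with the block), complement and acute phase -0.09 with shRela-1 (0.668), NRF2 -0.06 with shRela-2 (0.388), antigen presentation 0.09 with shRela-2 (0.668) and matrix -0.02 with shRela-2 (0.94). With the block and an estimated correlation, camera gave 0.577 for cholesterol synthesis and 0.507 for lysosome with shRela-1. With the block, camera also called cholesterol synthesis in the mean contrast (0.00504 against 0.125, and 0.507 with an estimated correlation). Without the block, 5 of its 25 members fell and 1 rose in that contrast (median -0.12). Among the 21 members with neither AGGTGTA nor GAAGCTA, 1 fell and 1 rose (median -0.07). Between hairpins, camera with the block called complement (0.00886 against 0.0539), matrix (0.0142 against 0.0752), contractile genes (0.0192 against 0.101) and macrophage markers (0.00934 against 0.17). With an estimated correlation in the blocked model, camera's adjusted p for these lists were 0.272, 0.62, 0.596 and 0.372, and the calls were lost.

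Markers of cell types other than fibroblasts did not pass as lists without the block. Lyz2, the most abundant of the macrophage and blood markers, was at 366 ± 74.3 CPM in shScr, 345 ± 44.5 CPM in shRela-1 and 324 ± 78.3 CPM in shRela-2 (adjusted p = 0.503 for shRela-2, or 0.0012 with the block, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). This list had a median of 0.02 and a mean of -0.02 with shRela-1 (camera, adjusted p = 0.833). Endothelial markers had medians of -0.07 with shRela-1 and -0.05 with shRela-2 (camera, adjusted p = 0.999 and 0.999), with camera's direction up for shRela-1, and Flt1 stood at 103 ± 13.3 CPM in shScr. Epithelial markers had medians of 0.02 with shRela-1 and -0.22 with shRela-2 (camera, adjusted p = 0.723 and 0.833), with Krt19 at 10.8 ± 0.798 CPM in shScr. Skeletal muscle and cartilage markers had medians of 0.16 with shRela-1 and -0.12 with shRela-2 (camera, adjusted p = 0.668 and 0.999). Neural and glial markers had medians of -0.23 with shRela-1 and -0.09 with shRela-2 (camera, adjusted p = 0.388 and 0.85), with a mean of 0.07 for shRela-2. Adipocyte markers had medians of 0.32 with shRela-1 and 0.29 with shRela-2 (camera, adjusted p = 0.747 and 0.666).

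Of the 82 tested genes on the lists of NF-kB targets and SASP factors, 11 fell with both hairpins, against 2.33 at the rate of all tested genes, and the median in the mean contrast was -0.25, although SASP factors did not pass as a list with shRela-1 (median -0.09, camera, adjusted p = 0.157). Seed-matched silencing of the members may lower single genes. Still, the 72 members with neither AGGTGTA nor GAAGCTA also had a median of -0.25 (95% interval over genes from -0.34 to -0.19). That interval treats the genes as independent and does not cover the spread between samples. Of the 72, 63 were below 0 (camera on these alone, unadjusted p = 1.99e-07, and 0.0352 with an estimated correlation). Members with overlapping motifs, such as GGTGTAA or TGAAGCT, were not removed, so silencing through those was not tested. In 0 of 40 simulations of unchanged groups, as many members were called lower with both. At an unadjusted p under 0.05 by edgeR, 14 were observed and at most 3 simulated. The unadjusted counts argue against chance in the shared controls only for genes that vary independently. The simulations drew each gene on its own and without replicate effects, so chance shifts shared by the members were not covered. Deviations of same-numbered shScr and shRela samples from their group means had a lowest correlation of 0.189. The lowest between same-numbered samples of the 2 hairpins was 0.204. The numbers thus pair controls with knockdown samples. Group means were removed first, so an offset common to all controls cannot be seen, and controls grown as separate cultures stay open. A library batch that goes with the tag in the titles of the shScr samples cannot be told apart from the knockdown, since it holds all controls and no other sample, and an effect of Rela on these genes stays a hypothesis beside it.

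For shRela-1 against shScr, 1 of the 10 splits, the real one, called as many genes (3491, highest other 0 by edgeR; 5367 and 998 at an unadjusted p under 0.05). For shRela-2 it was also 1 of 10 (4561, highest other 0 by edgeR; 6019 and 833 at an unadjusted p under 0.05). In both comparisons the 3 other splits with each replicate number once called at most 0 genes by edgeR and at most 121 at an unadjusted p under 0.05, and 10 splits cannot give a share under 0.05. For the mean contrast, fitted as 6 knockdown against 3 control samples, 3 of 84 splits called as many as the real 440. Among the splits that take each replicate number once, as the real one does, it was 3 of 27, a share of 0.111, so chance is not excluded once the pairing of the samples is kept. The other 2 of these called 3849 and 2692 genes and set shRela-2 or shRela-1 against all other samples, which points to a structure of the samples by hairpin, and the next highest of all splits called 88. For genes changed in the same direction by both hairpins, 4 of 100 splits called as many as the real 1070, with 2135 as the highest other. Among the 12 of these splits that take each number once in every group it was 3, a share of 0.25, so the splits alone do not exclude chance there either. The 3 others of the 100 (2135, 1977 and 1179) kept all samples of 1 hairpin together as the common reference and mixed the remaining samples, which again points to the structure by hairpin, and the next called 15. Simulated unchanged groups against the same controls gave at most 0 such genes with the unblocked dispersions and 7 with the blocked ones. The observed count by the same unblocked fit was 1070. Adjusted calls in groups without any change are few by construction, so these counts do not decide. At an unadjusted p under 0.05 by edgeR, 1753 genes were observed, and at most 182 were simulated with the unblocked dispersions. This argues only against sampling noise of independent genes, since the simulations held no correlation between genes and no replicate effect.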
